A study of Mus musculus with 12 samples.

How the data were processed

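The deposited table held raw UMI counts (unique molecular identifiers, 1 per captured transcript molecule) for each gene and well, with no normalisation, for 1150 wells on 12 plates of 96-well format; 2 plates had 95 wells in the table. It had 50508 gene models, of which 26350 had at least 1 UMI, and every one carried a mouse gene name. Per the labels, lysis and reverse transcription took place in the wells, and libraries were made with Nextera XT. The authors named STAR 2.5.3a, featureCounts 1.5.3 and the builds GRCm38 and GRCh38, without stating the role of each; how molecules were collapsed and which wells were dropped before deposition are not stated. No read files were used here. Gene positions came from the GENCODE vM21 annotation of GRCm38.

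The labels gave each plate its sorting gate (CD49b− neuronal or CD49b+ glial cells), its treatment and the mouse identifiers of its pool. The plates formed 4 groups of 3, and the CD49b− and CD49b+ plates with the same replicate number came from the same pool of 2 mice. Residuals of the CD49b− and CD49b+ plates of 1 pool correlated across 8555 genes at 0.0971, 0.0431 and 0.0587 in homeostasis and at 0.184, 0.113 and −0.0336 after irradiation; genes are not independent replicates. With CD49b+ plates of other pools of the treatment the highest correlation was −0.0496, 1.74e-04 and 0.0103 in homeostasis and −0.0697, 0.115 and 0.0582 after irradiation. The main gene tests did not pair the gates by pool, and the pool as a block was an alternative fixed beforehand. The plates were placed in 3 run sets inferred from position and plate numbers in the labels, which do not say whether these are sequencing runs. Set A held replicate 1 of both treatments, set B irradiated replicates 2 and 3, and set C homeostasis replicates 2 and 3. Only set A holds both treatments, so a fit with the run set as a term takes the irradiation effect, averaged over the gates, from 1 pool of each treatment.

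A well was retained with at least 1000 UMIs, at least 500 genes detected and under 20% of its UMIs from mitochondrial genes, which left 964 wells and 5119450 of the 5159668 UMIs. Retained wells were scaled to 10000 UMIs, log-transformed, reduced to 2000 highly variable genes and 30 principal components, and clustered with 15 neighbours and Leiden resolution 1.0 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15, seed 0). A cluster took the name of the neuron or glia marker set fixed before the data were examined if that set had the highest mean detection of the 13 sets, at least 3 of its markers were detected in at least 10% of the wells, and no other set held more of the cluster's 10 leading genes; otherwise it stayed unnamed. Shares of wells per class were compared between gates with a two-sided exact sign-flip permutation test over 6 pools, and between treatments with a two-sided exact permutation test of 3 plates against 3.

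UMI counts were summed per plate over retained wells, or per plate over the wells of 1 class, leaving out sums of fewer than 10 wells. Sums were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr, 4 group means sharing 1 dispersion, quasi-likelihood F tests and Benjamini-Hochberg adjustment over all genes tested, at 0.05. The contrasts were CD49b+ minus CD49b− averaged over treatments, irradiated minus homeostasis within each gate or class, and the difference between the irradiation effects (interaction). The same settings, tested on simulated data of the same size and depth, recovered 83 of 100 genes changed 4-fold and 31 of 100 changed 2-fold for irradiation in CD49b− plates, 67 and 13 in CD49b+ plates, 89 and 47 for the gate, and 40 and 2 for the interaction. For sums by class they recovered 81 and 23 for neuron-like cells, 46 and 11 for glia-like cells and 26 and 2 for the interaction. Simulated counts were independent draws at the dispersion trend, without effects of pool, run set or stray wells. Recovery in the real data may therefore be lower.

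Levels are TMM-normalised CPM, UMI counts scaled to a common library size over the tested genes, with the SD over plates. Where all plates of a group had 0 UMIs, a fold is given as a lower bound against a floor of 3 counts per plate, and where a group held 1 to 3 UMIs, as a ratio with an exact 95% binomial counting interval; both use CPM scaled to all retained UMIs of a plate and cover counting error only. Values within run set A use the same scale. Chance alone separates the plates of 3 against 3 completely in 10% of genes.

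Before the data were examined, 22 gene lists were fixed: p53 targets, DNA repair, apoptosis machinery, cell cycle, interferon response, antigen presentation, cytokines and NF-kB response, immediate early genes, heat shock, unfolded protein and integrated stress response, reactive glia, neural crest and progenitor, neurite outgrowth, neurotransmitters and neuropeptides, synaptic vesicle machinery, neuronal ion channels and receptors, myelin and Schwann, oxidative phosphorylation, glycolysis and hypoxia, cholesterol biosynthesis, extracellular matrix, and trophic and niche factors. The 13 marker sets covered neuron, glia, smooth muscle, interstitial cell of Cajal, fibroblast, pericyte, endothelial, macrophage, lymphocyte, epithelial, tuft, mesothelial and erythroid cells. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at its preset correlation and adjusted over the lists of a contrast; an estimated correlation and fry were alternatives. Named genes followed a rule fixed at the same time: Dclk1 and Itga2 always; the 10 genes with the largest change in each direction among those past 0.05 whose plates separated completely and whose mean log2 CPM was at least 5; from each list and marker set, up to 4 members past 0.05 with the smallest p, or if none passed the 2 with the highest expression; and, where no gene passed, the 6 with the smallest p. Genes named outside that rule are said to have been chosen after their values were seen.

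Alternatives fixed before the data were examined were RLE normalisation, DESeq2 1.42.0, no filter beyond 1 count, all wells with at least 1 UMI (500 UMIs for shares), stricter wells (2000 UMIs and 1000 genes), removal of wells above 3 times their plate median, thinning of each well to 1000 UMIs, the run set or the age at tamoxifen (8 or 9 weeks) as a term, the mouse pool as a block, a fit of only the 2 groups compared, Leiden resolutions 0.5 and 2.0, and leaving out each pool. A pair was added after seeing the data: the plates without the 4 neuron-like wells sorted as CD49b+, and the unnamed clusters put with the class whose markers they held. For the named genes, the share of their 31-base words found in another gene model was computed from the GENCODE transcripts. The result of 1 gene that the naming rule picks is not reported here.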

Results

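Cells were sorted one per well from preparations of the longitudinal muscle and myenteric plexus (LMMP) of the intestine of adult C57BL/6 mice, the layer that holds the myenteric neurons and glia of the gut's own nervous system. All carried the Dclk1-tdTom label, a red fluorescent reporter tied to Dclk1, the gene of a doublecortin-like kinase that binds microtubules. Surface CD49b, the integrin alpha 2 chain encoded by Itga2, split them into CD49b− cells, called neuronal in the labels, and CD49b+ cells, called glial. Mice received 3 mg tamoxifen and were left in homeostasis or irradiated with 10.5 Gy 7 days later. All tissue was collected 10 days after tamoxifen, which is 3 days after irradiation. Each of the 4 groups had 3 plates, each from a pool of 2 mice, so that 6 mice stood behind each treatment. Total UMIs per plate ran from 543087 to 747272 for CD49b− plates and from 154993 to 245922 for CD49b+ plates. The well filter retained 262 of 288 homeostasis CD49b− wells, 266 of 287 irradiated CD49b− wells, 223 of 288 homeostasis CD49b+ wells and 213 of 287 irradiated CD49b+ wells. The plate median of UMIs per retained well averaged 7590 ± 1091 (SD, n = 3) and 7035 ± 982 on homeostasis and irradiated CD49b− plates, and 2445 ± 298 and 2469 ± 132 on the CD49b+ plates.

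The question of which cells each gate held was addressed by clustering. Neuron-like cells made up 90.8% ± 4.29 (SD, n = 6 pools) of retained CD49b− wells and 0.198% ± 0.486 of CD49b+ wells. Glia-like cells made up 82.8% ± 38.4 of CD49b+ wells and 0% of CD49b− wells. Both differences had the same sign in 6 of 6 pools, with a two-sided exact sign-flip permutation p of 0.03125, the smallest that 6 pools allow. Of the 8 clusters, 4 were neuron-like (188, 79, 83 and 130 wells), with Calb2 and Sst, Npy and Nos1, Tac1 and Penk, or Cartpt and Vip among their leading genes. These encode a calcium-binding protein, neuropeptides and the nitric oxide synthase of neurons. A further 2 were glia-like (213 and 151 wells), and 2 stayed unnamed. The first held 52 wells with neuron markers, among whose leading genes the fibroblast marker Dcn also stood. The other held 68 wells with glia markers, of which 65 lay on the plate of irradiated CD49b+ replicate 1. Its leading genes were H2-Ab1, a major histocompatibility complex (MHC) class II gene, the neuropeptide gene Grp and the gene model Gm37895. Wells were clustered without batch correction, so a trait of that plate cannot be told from a kind of glia. With the unnamed clusters put with the class whose markers they held, 100% of CD49b− wells were neuron-like and 99.2% ± 1.46 of CD49b+ wells glia-like. By the naming rule, neuron-like cells made up 44.2% ± 4.06 of stricter CD49b− wells and 57.0% ± 10.7 of those with at least 500 UMIs. There, more clusters with neuron markers stayed unnamed.

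Whether irradiation shifted these shares was tested with 3 plates against 3, where an exact permutation p cannot go below 0.1. Neuron-like cells were 92.5% ± 2.38 (SD, n = 3) of homeostasis and 89.1% ± 5.65 of irradiated CD49b− wells (two-sided exact permutation p = 0.4). Glia-like cells were 99.2% ± 1.43 of homeostasis and 66.4% ± 53.7 of irradiated CD49b+ wells (exact permutation p = 0.2). Without irradiated replicate 1, whose wells fell into the unnamed glia cluster, the latter difference was −1.80 percentage points. Neuron-like wells, counted with the unnamed clusters put with their class, appeared on 2 irradiated CD49b+ plates: 1 well of 24748 UMIs on replicate 1 and 3 wells of 12699, 13170 and 11627 UMIs on replicate 2.

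**Figure D1:**
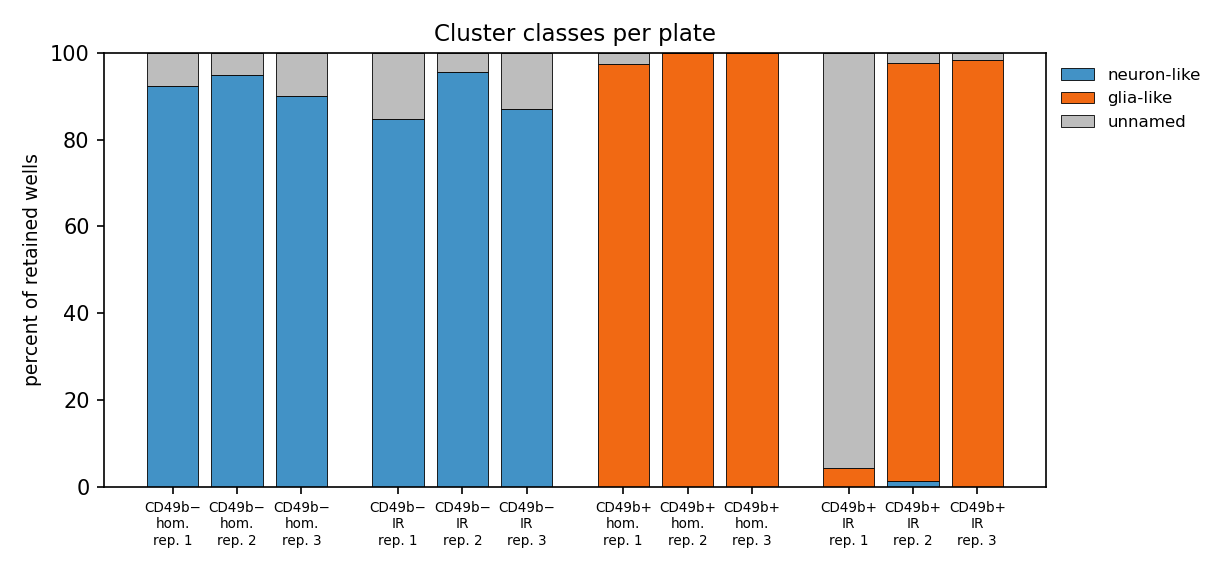
Percent of retained wells (vertical axis, 0 to 100) that were neuron-like, glia-like or unnamed, as stacked bars for each of the 12 plates in their 4 groups. Neuron-like wells averaged 90.8% on CD49b− plates, and 65 of the 68 wells of the unnamed glia cluster lay on the plate of irradiated CD49b+ replicate 1.

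The comparison of the gates asked how the CD49b+ (glial) and CD49b− (neuronal) fractions of Dclk1-labelled cells differ. All 10 tested glia markers were higher in CD49b+ cells, and all 11 tested neuron markers were lower. S100b, a calcium-binding protein of glia, stood at 1206 ± 180 CPM (SD, n = 3) on homeostasis CD49b+ plates and 47.1 ± 4.35 on CD49b− plates. Gfap, the intermediate filament of glia, stood at 456 ± 5.01 CPM in homeostasis and 962 ± 317 after irradiation on CD49b+ plates, where it had 736 UMIs against 1 on CD49b− plates, a ratio of 2624 (95% counting interval 470 to 103800). Snap25, part of the machinery that fuses synaptic vesicles, stood at 1748 ± 110 CPM on homeostasis CD49b− and 9.25 ± 2.88 on CD49b+ plates. Apoe, a lipid carrier of glia, reached 29866 ± 2110 CPM on homeostasis CD49b+ plates against 80.8 ± 106 on CD49b− plates.

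Of 8555 genes tested with edgeR, 2536 were higher and 2775 lower in CD49b+ cells. The log2 fold change was 4.61 (SE 0.183, adjusted p = 8.42e-16) for S100b, 9.65 (SE 0.510, adjusted p = 9.08e-14) for Apoe and −5.50 (SE 0.383, adjusted p = 1.62e-11) for Snap25, each with the same sign in 6 of 6 pools and so in each run set. Itga2, the gene of the sorting antigen, had 0 UMIs on the 6 CD49b− plates and 20.7 ± 16.9 CPM on homeostasis CD49b+ plates, at least 4.67-fold higher. Dclk1 was lower in CD49b+ cells at 79.9 ± 12.8 CPM against 148 ± 5.87 in homeostasis, and 49.4 ± 2.32 against 157 ± 19.7 after irradiation (log2 fold change −1.27, SE 0.199, adjusted p = 7.87e-06). Cells of both gates were sorted as Dclk1-tdTom+, and surface CD49b parted the gates. Dclk1 lies on chromosome 3 (55242364 to 55539068, plus strand, GRCm38) and Itga2 on chromosome 13 (114833081 to 114932100, minus strand).

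Other genes with the largest differences toward CD49b+ cells were Tmprss5, encoding a membrane serine protease, with 626 UMIs against 1 (ratio 2232, 95% counting interval 399 to 88280), and Sox10, a transcription factor of glia and neural crest (ratio 586, 161 to 4863). Fam107a had 307 UMIs against 1. Col12a1, a collagen chain, had a log2 fold change of 9.19 (SE 0.385). Fxyd3, a regulator of the sodium pump, was at least 43.1-fold higher, though 41.0% of its 31-base words also occur in another gene model. Toward CD49b− cells stood Vip, vasoactive intestinal peptide (log2 fold change −8.08, SE 0.513), Bglap, osteocalcin (at least 74.1-fold lower in CD49b+ cells; 62.9% of its 31-base words shared), and Ly6c1, a surface antigen (at least 22.9-fold; 46.8% shared). Others were Sst, somatostatin (at least 13.5-fold, but 3.22-fold without irradiated replicate 2), Adcyap1r1, the receptor of the peptide PACAP (at least 5.02-fold), Gucy1b3, a subunit of the nitric oxide receptor (at least 4.90-fold), and Jph4, a junctophilin (at least 4.87-fold). Cox8b, Bglap2 and Ociad2 each had 1 UMI on CD49b+ plates against 1212, 1155 and 774.

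**Figure D2:**
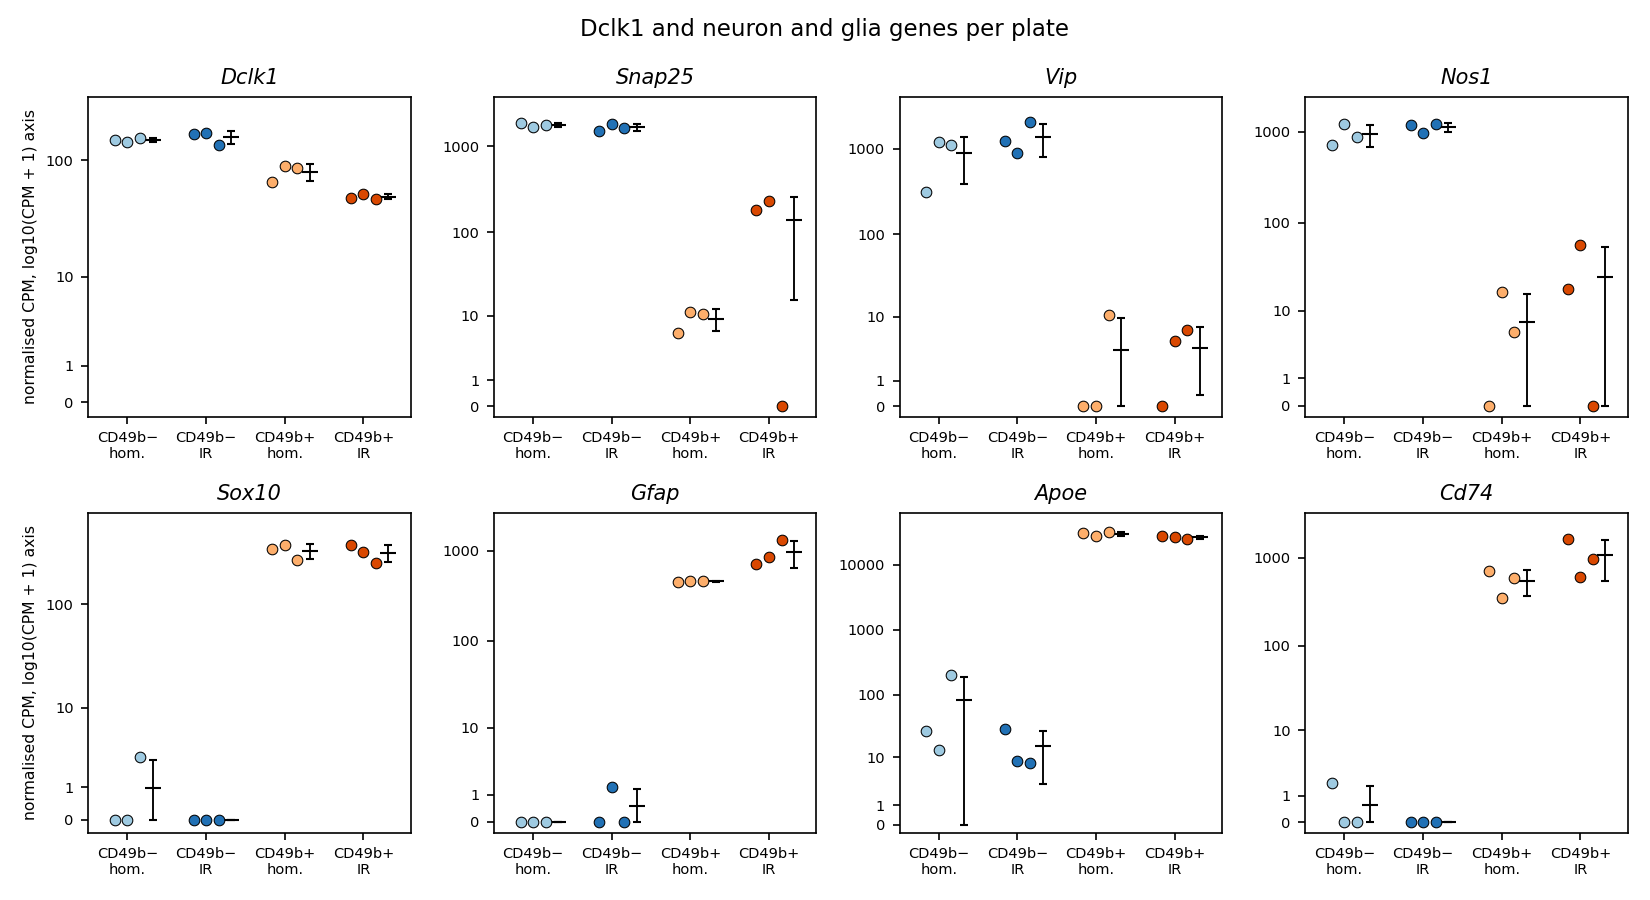
Normalised UMI counts (vertical axis, log10 of CPM + 1) of Dclk1, Snap25, Vip, Nos1, Sox10, Gfap, Apoe and Cd74 in each of the 4 groups. Points are plates, and the line with its bar is the mean ± SD (n = 3). Sox10, Gfap, Apoe and Cd74 lay higher on all 6 CD49b+ plates than on the 6 CD49b− plates, and the other genes lower.

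Genes of immunity were higher in CD49b+ cells. All 14 tested antigen presentation genes were higher, among them B2m, the light chain of MHC class I (6237 ± 344 CPM against 302 ± 71.5 in homeostasis), H2-Ab1 and H2-Eb1, chains of MHC class II (log2 fold change 9.12, SE 0.438, and 7.89, SE 0.337), and Cd74, the class II invariant chain, with 835 UMIs against 1. Of 16 interferon response genes 14 were higher, including the ubiquitin-like Isg15 (6.26, SE 0.321) and Ifit3 (5.43, SE 0.401), whose words are 61.8% shared with another model. Of 10 cytokine and NF-kB genes 9 were higher, including the NF-kB inhibitor Nfkbia (4.89, SE 0.297) and the chemokine Cxcl10 (at least 41.6-fold). Immediate early genes, which respond within minutes to stimulation and to tissue dissociation, were higher in 16 and lower in 1 of 18, with Socs3 (4.74, SE 0.190), Nr4a1 (4.87, SE 0.218), Klf2 (4.92, SE 0.288) and the RNA-decay factor Zfp36 (4.38, SE 0.201). The camera adjusted p was 6.2e-21 for antigen presentation, 1.01e-08 for interferon, 4.15e-07 for cytokines and 2.03e-12 for immediate early genes.

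Glial and matrix lists were also higher in CD49b+ cells: neural crest and progenitor genes (8 higher, 2 lower of 11; adjusted p = 4.52e-08) with the Notch target Hes1 (log2 fold change 6.21, SE 0.238) and the endothelin receptor Ednrb (3.38, SE 0.221). Reactive glia genes (5 higher, 3 lower of 8; adjusted p = 3.91e-05) included Serpina3n, a protease inhibitor (4.65, SE 0.240), and extracellular matrix genes (8 of 10 higher; adjusted p = 9.75e-06) included Sparc (4.55, SE 0.197). Glia markers as a list had an adjusted p of 9.76e-22 and neuron markers of 1.12e-11. All 14 synaptic vesicle genes and all 14 neuronal ion channel and receptor genes were lower (adjusted p = 2.07e-11 and 5.64e-09), with Syn2, a synapsin (−7.03, SE 0.480), and Chrna3, a nicotinic receptor subunit (−7.29, SE 0.464). Of 16 neurotransmitter and neuropeptide genes 13 were lower and 1 higher (adjusted p = 2.79e-08), including Slc18a3, the vesicular acetylcholine transporter (−7.20, SE 0.511), Nos1, the neuronal nitric oxide synthase (−6.10, SE 0.345), and Calb2, calretinin (−6.71, SE 0.307). These 8 lists and the 4 of immunity kept their call with an estimated correlation, 6 of the 12 also with the mouse pool as a block. Neurite outgrowth (8 lower, 3 higher of 11; adjusted p = 0.00222), oxidative phosphorylation (14 of 18 lower; 6.24e-04), glycolysis (7 lower, 1 higher of 10; 0.0012) and cholesterol biosynthesis (13 of 15 lower; 0.0157) lost it. They had adjusted p of 0.0530, 0.281, 0.0530 and 0.213 with an estimated correlation. Examples were Map1b, a microtubule-associated protein of axons (−3.07, SE 0.214), Cox5a of cytochrome c oxidase (−1.72, SE 0.189), the glycolytic enzymes Ldha (−2.82, SE 0.170) and Aldoa (−2.14, SE 0.185), and Fdft1, squalene synthase (−2.34, SE 0.237).

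Other lists did not pass in camera: p53 targets (5 higher, 1 lower of 11; adjusted p = 0.115), DNA repair (1 higher, 2 lower of 6; 0.7999), apoptosis machinery (2 higher, 2 lower of 6; 0.802), heat shock (4 higher, 7 lower of 12; 0.414) and the unfolded protein response (3 higher, 3 lower of 11; 0.794). The median and mean log2 fold change differed in sign in the apoptosis list (−0.24 and 0.29), the heat shock list (−0.75 and 0.68) and the unfolded protein response list (0.15 and −0.15), and the test pointed up in each. Members past the threshold included Cdkn1a, the p53-induced inhibitor of the cell cycle (3.55, SE 0.313), the anti-apoptotic Bcl2 (2.53, SE 0.310), Hspa1a, an inducible chaperone (3.99, SE 0.257; 70.1% of its words shared with Hspa1b), and Asns, asparagine synthetase (−4.60, SE 0.346). Counts adjusted over the list alone equalled those over all genes in every list except glycolysis, where 2 members were higher instead of 1. Lists with fewer than 5 tested genes were not tested as lists. Of smooth muscle genes Myl9 and Acta2 were higher and Synpo2 lower in CD49b+ cells. Etv1 of the interstitial cell of Cajal set was lower. It was detected in 120 of 262 homeostasis CD49b− wells, where Kit and Ano1 of that set were detected in 1 well each. Etv1 therefore does not mark such cells here. Col3a1 of fibroblasts was higher, and the macrophage markers Cd74 and Cd14 were higher. Tyms of the cell cycle list was lower, Mbp was higher and Cnp lower among 3 myelin genes, and 3 of 4 trophic factors were higher, including Tgfb2, with Nrg1 lower. No pericyte, endothelial, lymphocyte, epithelial, tuft, mesothelial or erythroid marker was expressed highly enough to be tested. CD49b− wells held more UMIs than CD49b+ wells, and with each well thinned to 1000 UMIs 1561 of 2417 tested genes passed. With the mouse pool as a block and an estimated correlation, 6 of the lists passed in place of 12. The lists that no longer did were neuron markers (adjusted p = 0.0803), immediate early genes (0.0656), synaptic vesicle and matrix genes (0.0735 each), and interferon response and ion channel genes (0.05004 each).

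Irradiation of CD49b− cells was compared to learn which transcripts of the neuronal fraction changed 3 days after acute injury. Gm10800 and Gm10801, repeat-like gene models of unknown function on chromosome 2, rose from 2.18 ± 1.02 to 113 ± 23.9 CPM (SD, n = 3) and from 0.558 ± 0.966 to 85.3 ± 37.4 CPM. A330069E16Rik, a long intergenic non-coding RNA on the same chromosome, rose from 36.2 ± 8.70 to 146 ± 63.6 CPM. Gm21738, a related model on chromosome 14 chosen after its values were seen, had 0 UMIs on the homeostasis plates and 46.5 ± 20.4 CPM after irradiation, at least 9.37-fold higher. Each of these lay higher on all 3 irradiated than on all 3 homeostasis CD49b− plates.

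These were the 4 genes past the threshold of 8555, and none was lower. In edgeR 354 had an unadjusted p below 0.05, no more than chance alone would give. DESeq2 also called 4. The log2 fold change was 5.52 for Gm10800 (SE 0.495, adjusted p = 5.6e-07) and 1.99 for A330069E16Rik (SE 0.343, adjusted p = 0.0123), while Gm10801 had 152 UMIs against 1, a ratio of 154 (95% counting interval 27.2 to 6126; adjusted p = 4.7e-06). Gm10800 lies at 98666547 to 98667301 (minus strand) and Gm10801 at 98662237 to 98664083 (plus strand) on chromosome 2, Gm21738 at 19415857 to 19418930 (minus strand) on chromosome 14, and A330069E16Rik at 91237146 to 91238352 (plus strand) on chromosome 2. Of the 31-base words of Gm10800, Gm10801 and Gm21738, 42.0%, 36.2% and 43.6% also occur in other gene models. Within run set A, the set with both treatments, Gm10800 went from 1.64 to 111 CPM, Gm10801 from 0 to 96.0, Gm21738 from 0 to 55.4 and A330069E16Rik from 42.6 to 168.

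No list had a member past the threshold over all genes in irradiated CD49b− cells, and 5 lists shifted in camera. Interferon response (16 genes, adjusted p = 2.92e-07), antigen presentation (14 genes, 0.00567) and neurotransmitter genes (16 genes, 0.0238) shifted upward, and immediate early genes (18 genes, 3.93e-05) and cholesterol biosynthesis (15 genes, 1.4e-05) downward. With an estimated correlation their adjusted p was 0.262, 0.374, 0.303, 0.374 and 0.262. Adjusted over the list alone, 2 immediate early genes were lower and 1 neurotransmitter gene was higher. B2m stood at 302 ± 71.5 and 488 ± 36.3 CPM (log2 fold change 0.69, SE 0.234, adjusted p = 1), and Hmgcs1, an early enzyme of cholesterol synthesis, at 318 ± 77.7 and 220 ± 52.6 (−0.53, SE 0.245, adjusted p = 1). None of 11 p53 targets passed (adjusted p = 0.837), and DNA repair and apoptosis genes had adjusted p of 0.486 and 0.980. Dclk1 had a log2 fold change of 0.08 (SE 0.215, adjusted p = 1).

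Summing neuron-like cells alone gave 10 genes higher and 2 lower after irradiation of 9923. Gm10800 rose again, from 1.84 ± 1.77 to 123 ± 30.96 CPM (log2 fold change 5.87, SE 0.524, adjusted p = 3.94e-09), as did Gm10801 (adjusted p = 6.23e-08) and A330069E16Rik (1.90, SE 0.3196, adjusted p = 0.00175). Cd24a, a surface glycoprotein, rose from 124 ± 28.2 to 272 ± 71.1 CPM (1.13, SE 0.233, adjusted p = 0.0260), and the neuropeptide gene Cartpt from 1974 ± 1175 to 5152 ± 2328 (1.38, SE 0.302, adjusted p = 0.0479), with overlapping plates. Avpr1a, the vasopressin receptor of smooth muscle and neurons, fell from 61.1 ± 22.98 to 13.6 ± 2.43 CPM (−2.15, SE 0.422, adjusted p = 0.0222), and Gamt, which makes creatine, from 38.8 ± 2.53 to 8.72 ± 5.36 (−2.09, SE 0.444, adjusted p = 0.0376). The others were 4930528J11Rik (1.28, SE 0.280, adjusted p = 0.0479) and Gm21738, Gm10717, Gm12155 and Gm19244, these last chosen after their values were seen. Of the lists, cholesterol biosynthesis (adjusted p = 8.26e-06), immediate early genes (1.25e-04) and glycolysis (0.0202) shifted down, and interferon response (9.79e-04), antigen presentation (0.0367) and neurotransmitter genes (0.00798; 1 of 14 higher, 4 adjusted over the list alone) up. None held with an estimated correlation, where the smallest adjusted p was 0.171.

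In the CD49b− plates 17 genes passed without irradiated replicate 1, 45 without a count filter, 7 with the 2 groups alone and 0 with thinned wells, where 98 had an unadjusted p below 0.05, and A330069E16Rik lost its call with the run set as a term and without any homeostasis replicate or irradiated replicate 3 (adjusted p 1.48e-06 to 0.354 over its 16 alternatives). In neuron-like cells 35 passed without irradiated replicate 1, 7 and 6 without homeostasis replicates 1 and 2, 38 without a filter and between 3 and 6 with DESeq2, thinning, all wells of at least 1 UMI, stricter wells, the run set as a term, the 2 groups alone or Leiden resolution 0.5, and Cd24a passed in 7 of 19 alternatives (adjusted p 0.00154 to 1), Cartpt in 8 of 19 (1.4e-11 to 1), 4930528J11Rik in 6 of 19 (1.66e-05 to 1), Avpr1a in 8 of 17 (5.49e-04 to 0.601) and Gamt in 6 of 18 (0.00592 to 0.9897).

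**Figure D3:**
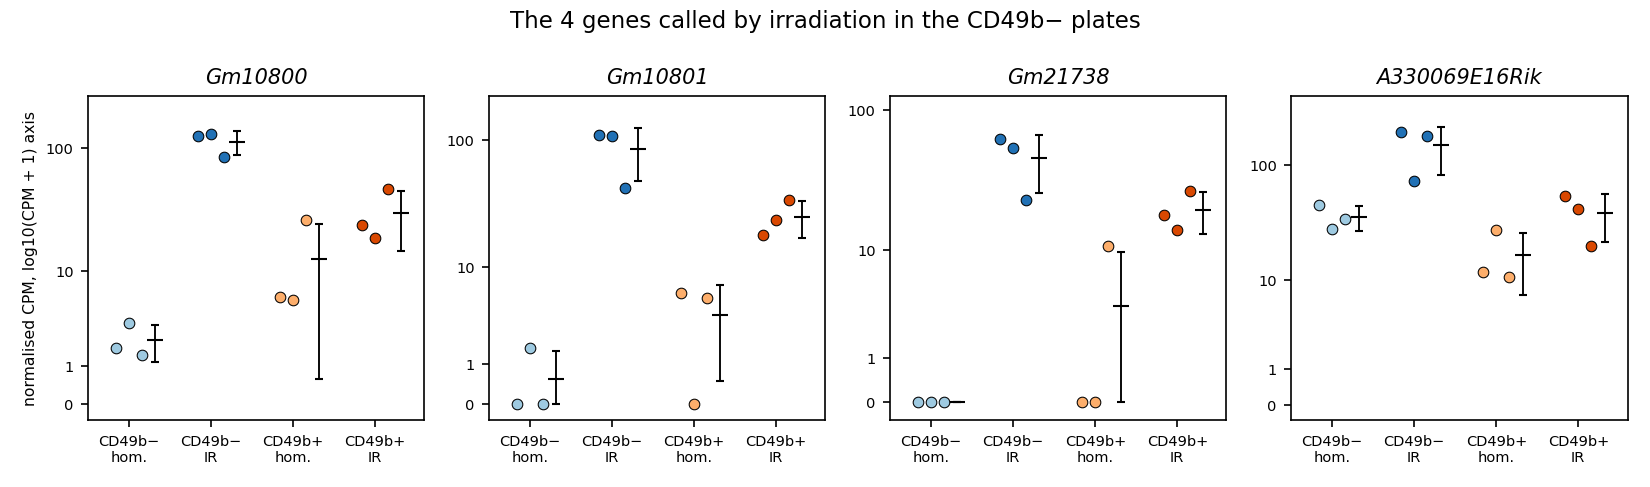
Normalised UMI counts (vertical axis, log10 of CPM + 1) of Gm10800, Gm10801, Gm21738 and A330069E16Rik in each of the 4 groups. Points are plates, and the line with its bar is the mean ± SD (n = 3). On CD49b− plates Gm10800 stood at 2.18 CPM in homeostasis and 113 after irradiation, and on CD49b+ plates at 12.8 and 30.3.

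Irradiation of CD49b+ cells was compared to learn how the glial fraction responded to the same injury. Serpina3n, a protease inhibitor made by reactive astrocytes, rose from 148 ± 63.9 to 1466 ± 198 CPM (SD, n = 3), and Cdkn1a, the p53-induced inhibitor of the cell cycle, from 150 ± 132 to 649 ± 103. Of the MHC class II genes H2-Aa rose from 195 ± 69.6 to 645 ± 237 CPM and H2-Eb1 from 319 ± 51.8 to 864 ± 459, while H2-Ab1 (838 ± 245 to 2157 ± 1422, adjusted p = 0.0830; chosen after its values were seen) and the class II chaperone Cd74 (550 ± 182 to 1074 ± 522, adjusted p = 0.199) did not pass. Psmb8, a subunit of the immunoproteasome, rose from 276 ± 43.8 to 645 ± 187. Bst2, the interferon-induced tetherin, rose from 80.4 ± 4.63 to 299 ± 36.1 CPM, and Gfap from 456 ± 5.01 to 962 ± 317. Ctgf, a matricellular growth factor, fell from 214 ± 19.2 to 77.0 ± 45.4 CPM, and Slc35a2, the UDP-galactose transporter, from 122 ± 39.0 to 25.5 ± 10.8. Each of those past the threshold lay on the same side on all 3 irradiated plates.

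In all, 57 genes were higher and 4 lower, and 910 of 8555 had an unadjusted p below 0.05. The log2 fold change was 3.32 for Serpina3n (SE 0.278, adjusted p = 1.44e-07; chromosome 12, 104406729 to 104414329), 2.13 for Cdkn1a (SE 0.382, adjusted p = 0.00666), and 1.73 for H2-Aa (SE 0.308, adjusted p = 0.00733). It was 1.23 for Psmb8 (SE 0.250, adjusted p = 0.0145), 1.90 for Bst2 (SE 0.360, adjusted p = 0.0104) and 1.07 for Gfap (SE 0.244, adjusted p = 0.0380). H2-Eb1 (1.43, SE 0.279; 0.81 without irradiated replicate 1), H2-T23 of MHC class I (1.37, SE 0.300) and Fcgr2b, the inhibitory Fc receptor (4.15, SE 0.497), had adjusted p of 0.0114, 0.0265 and 2.92e-04. The lower genes were Slc35a2 (−2.20, SE 0.438, adjusted p = 0.0126), Brix1 of ribosome assembly (−1.78, SE 0.416, adjusted p = 0.0389), Ctgf (−1.52, SE 0.348, adjusted p = 0.0377) and Ptx4, a pentraxin (−2.49, SE 0.585, adjusted p = 0.0419). Ptx4 was chosen after its values were seen. So were Serping1, the inhibitor of complement C1, from 460 to 1375 CPM, and Tmem176a (1.43, adjusted p = 0.00666), Tmem176b, Ggta1 and Slc14a1, all higher. Within run set A, Serpina3n went from 189 to 1479 CPM, Cdkn1a from 293 to 683, H2-Aa from 241 to 813, Psmb8 from 287 to 742, Bst2 from 80.4 to 293, Gfap from 436 to 639, Slc35a2 from 80.4 to 16.3 and Ctgf from 224 to 48.8.

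By list, 2 of 8 reactive glia genes rose (3 adjusted over the list alone; camera adjusted p = 1.15e-07, and 0.00845 with an estimated correlation). Of 14 antigen presentation genes 4 rose (6 over the list alone; adjusted p = 1.15e-07), of 16 interferon genes 1 (8; 6.88e-08), of 11 p53 targets 1 (2; 0.00108) and of 11 unfolded protein response genes none (3; 1.26e-04). No extracellular matrix gene of 10 fell although the list shifted down (0.00177). With an estimated correlation these 5 had adjusted p of 0.0564, 0.0848, 0.0521, 0.0564 and 0.135. Hspa5, the chaperone BiP, stood at 773 and 1334.8 CPM (log2 fold change 0.79, SE 0.277, adjusted p = 0.243), and Sparc at 4649 ± 66.0 and 3220 ± 165 (−0.53, SE 0.238, adjusted p = 0.421). Glia markers (1 of 10 higher, adjusted p = 0.516), oxidative phosphorylation (0.0539), heat shock (0.0934), cytokines (0.232), DNA repair (0.839), apoptosis (0.255), immediate early (0.336), neural crest (0.133), glycolysis (0.120) and cholesterol genes (0.516) did not pass. Dclk1 stood at 79.9 ± 12.8 and 49.4 ± 2.32 CPM (−0.69, SE 0.349, adjusted p = 0.4998).

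**Figure D4:**
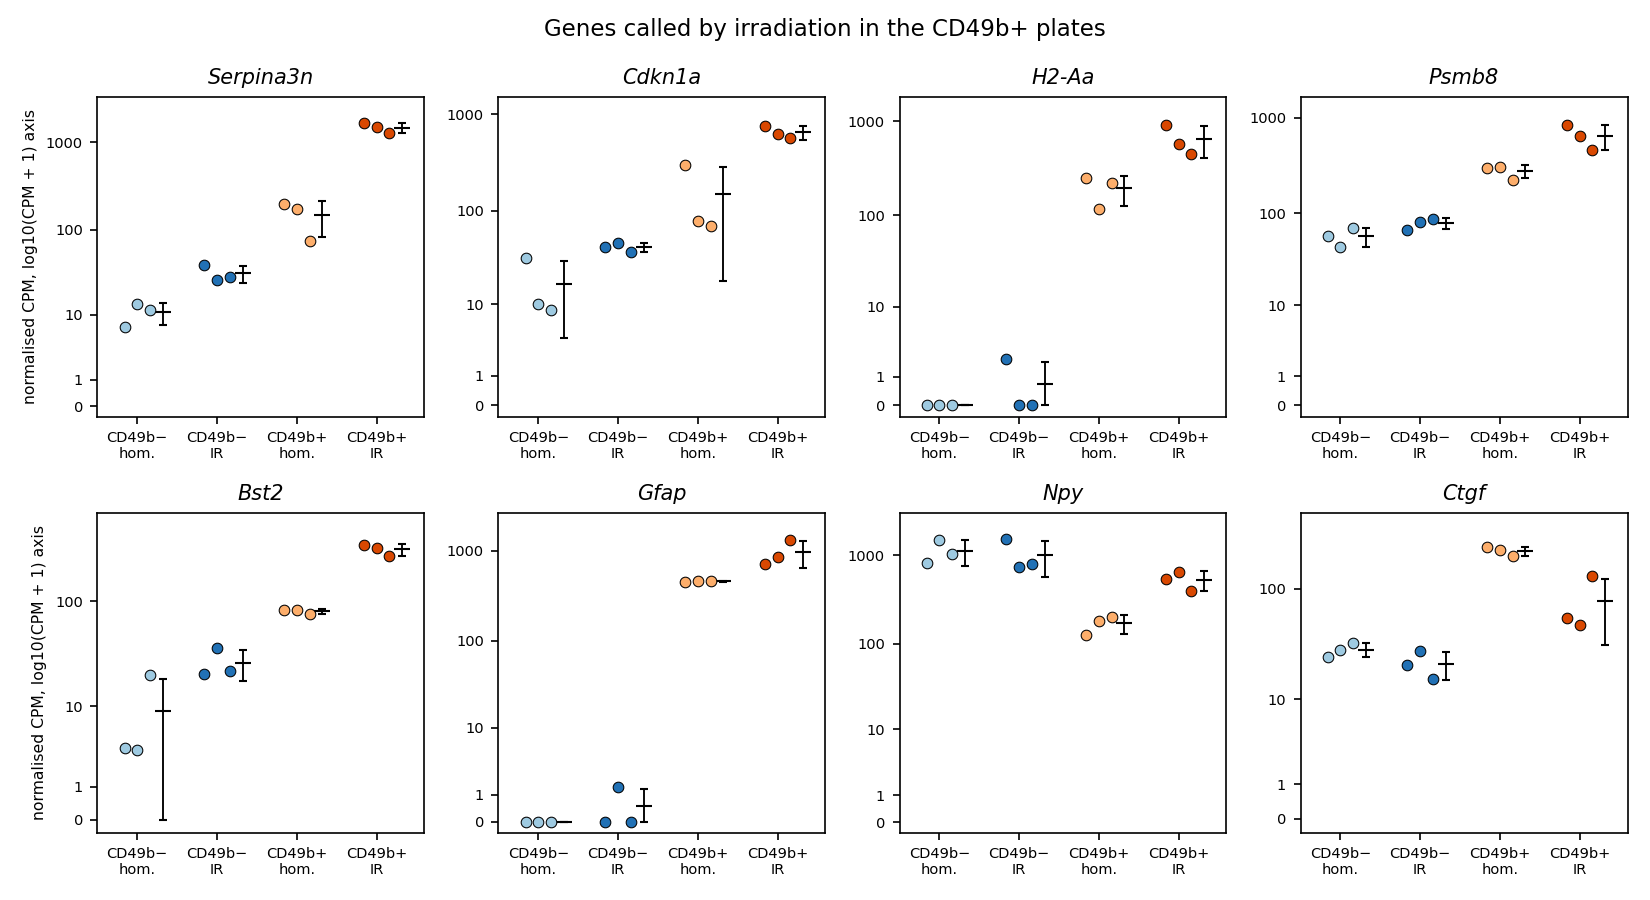
Normalised UMI counts (vertical axis, log10 of CPM + 1) of Serpina3n, Cdkn1a, H2-Aa, Psmb8, Bst2, Gfap, Npy and Ctgf in each of the 4 groups. Points are plates, and the line with its bar is the mean ± SD (n = 3). On CD49b+ plates Serpina3n stood at 148 CPM in homeostasis and 1466 after irradiation, and Ctgf at 214 and 77.0.

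Neuronal transcripts also rose on irradiated CD49b+ plates, 2 of which held the 4 neuron-like wells. Of the 57 higher genes, 44 were ones lower in CD49b+ than in CD49b− cells. Snap25 went from 9.25 ± 2.88 to 138 ± 122 CPM (log2 fold change 3.90, SE 0.774, adjusted p = 0.0124), and Prph, the peripheral neuron filament, from 14.7 ± 8.22 to 227 ± 245 (3.91, SE 0.762, adjusted p = 0.0114). The neuropeptide genes Cartpt (1127 UMIs against 1; ratio 1058, 95% counting interval 190 to 41810; adjusted p = 0.00796) and Gal, galanin (33.1 ± 27.8 to 9645 ± 16656 CPM, adjusted p = 0.0124), passed, but each rested mostly on 1 plate. Without irradiated replicate 1 the log2 fold change of Cartpt went from 10.02 to 4.68 (adjusted p = 0.245), and without irradiated replicate 2 that of Gal from 8.16 to −0.21 (adjusted p = 0.985). Grp went from 7.95 (adjusted p = 0.0320) to 0.42 (0.982) without irradiated replicate 1. Npy, neuropeptide Y, rose from 170 ± 41.1 to 529 ± 129 CPM on all 3 plates (1.63, SE 0.331, adjusted p = 0.0143). Resp18, a gene of neuroendocrine secretory granules chosen after its values were seen, had 449 UMIs against 1 (ratio 421, 75.3 to 16680). Htr3a, a serotonin receptor, was at least 3.79-fold higher and Ptprn, a granule phosphatase-like protein, at least 3.19-fold (2.752 and 2.181 at the lowest, with 1 irradiated plate left out). Stmn2, Stmn3, Syt1, Tubb3, Chgb, Fhod3, Eef1a2, Tro and Tmem41a also passed, each in 5 to 9 of 15 or 16 alternatives. By list, neuron markers (6 of 11 higher, 9 adjusted over the list alone; adjusted p = 2.27e-16), neurotransmitter genes (4 of 16, 8; 3.17e-05), neurite outgrowth (3 of 11, 4; 3.55e-04), synaptic vesicle (2 of 14, 6; 1.27e-04) and ion channel genes (1 of 14, 3; 0.00224) shifted up, with adjusted p of 0.0521, 0.0521, 0.0971, 0.200 and 0.220 with an estimated correlation. Without the 4 neuron-like wells, an alternative chosen after seeing the data, 22 genes passed, 19 of them among the 61. Of the 44 neuronal genes 5 stayed (Cartpt, Gal, Npy, Resp18 and Tmem176b), and of the other 13 higher genes 13. All 44 kept a positive log2 fold change, with a median of 2.19 (median SE 0.903) in place of 3.95 (0.864).

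The count rested on few plates: 13, 5 and 3 genes passed without homeostasis replicates 1, 2 and 3, 24 without irradiated replicate 2 and 144 without irradiated replicate 3. It was 30 with the run set as a term (26 of them shared), where Serpina3n kept its call (adjusted p 1.47e-26 to 1.06e-04 over its 17 alternatives) and Gfap (log2 fold change 0.66; 0.0130 to 0.579), Cdkn1a (1.30; 4.19e-09 to 0.119), H2-Aa (1.90; 5.65e-06 to 0.102), Psmb8 (1.30; 0.00188 to 0.171), Bst2 (2.16; 1.67e-04 to 0.113), Slc35a2 (−1.74; 8.62e-04 to 0.274) and Ctgf (−1.75; 0.00312 to 0.219) did not; it was 18 with thinned wells, 10 with the 2 groups alone, 112 with DESeq2 (52 shared) and 146 without a filter.

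Summing glia-like cells alone compared 3 homeostasis with 2 irradiated sums, since replicate 1 held 3 such wells, and gave 27 genes higher and 1 lower. Serpina3n rose from 141 ± 58.2 to 1403 ± 262 CPM (log2 fold change 3.32, SE 0.299, adjusted p = 4.98e-09), Gfap from 446 ± 7.98 to 1109 ± 248 (1.31, SE 0.222, adjusted p = 0.00169) and Cdkn1a from 145 ± 126 to 605 ± 83.8 (2.08, SE 0.349, adjusted p = 0.00119). The interferon-induced Ifi27l2a (1.91, SE 0.311, adjusted p = 8.35e-04), Ifit3 (1.69, SE 0.326, adjusted p = 0.00687) and Bst2 (1.85, SE 0.346, adjusted p = 0.00463) rose. So did H2-Aa (1.497, SE 0.292, adjusted p = 0.00799) and Psmb8 (adjusted p = 0.0403). Hspa5 rose from 761 ± 236 to 1618 ± 131 CPM (1.08, SE 0.231, adjusted p = 0.0196), and Npy from 168 ± 40.8 to 551 ± 233 (adjusted p = 0.00740). Wdr74, Fbxw11, Hspb8, a small heat shock protein, Gm12155 and Gal also passed, and Ptx4 was lower. Ptx4, Fcgr2b and Resp18 were chosen after their values were seen. Reactive glia genes shifted up (2 of 7 higher, 3 over the list alone; adjusted p = 1.59e-09, and 0.0330 with an estimated correlation). So did interferon (3 of 18, 9; 2.31e-15), antigen presentation (2 of 14, 5; 3.64e-09), unfolded protein response (1 of 11, 5; 7.56e-07), p53 targets (1 of 14, 3; 0.00646), neurotransmitters (2 of 14; 0.00217) and heat shock genes (0.0453). These last 6 had adjusted p of 0.0604, 0.0604, 0.0604, 0.165, 0.0604 and 0.419 with an estimated correlation.

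In glia-like cells 4 genes passed with the run set as a term, where Gfap and Ifi27l2a had negative log2 fold changes (−0.49 and −0.73) and the offset of set B comes from CD49b− plates, and 9 passed without irradiated replicate 2, without which Gal (−0.71) and Resp18 (−2.66) had negative ones. The count was 18, 17 and 18 without homeostasis replicates 1, 2 and 3, 17 with thinned wells or with the 2 groups alone, 15 at Leiden resolution 2.0 and 48 without a filter, and Wdr74 passed in 6 of 16 alternatives (adjusted p 0.0154 to 0.625), Fbxw11 in 5 of 17 (0.00663 to 0.903), Hspb8 in 5 of 18 (0.0168 to 0.585), Hspa5 in 7 of 18 (0.00115 to 0.761), Psmb8 in 8 of 18 (0.00978 to 0.932), Ifit3 in 9 of 18 (1.11e-06 to 0.903) and Ptx4 in 7 of 17 (0.00567 to 0.973).

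Whether the response to irradiation differed between the gates was tested by the interaction. Resp18 was the gene past the threshold (difference in log2 fold change 8.59, SE 1.44, adjusted p = 0.0326), while 649 of 8555 genes had an unadjusted p below 0.05. It had 187, 262 and 0 UMIs on irradiated and 0, 1 and 0 on homeostasis CD49b+ plates, higher on 2 of 3, and stood at 3144, 2825 and 3154 CPM on homeostasis and 3138, 2613 and 2790 on irradiated CD49b− plates. Snap25 (3.998), Syt1 (5.31) and Htr3a (7.16) did not pass (adjusted p = 0.0885 each), nor did Dclk1 (−0.77, SE 0.410, adjusted p = 0.718). In the camera test, with the 4 neuron-like wells in the sums, 11 lists differed between the gates, all upward for CD49b+ minus CD49b−. These included neuron markers (3.51e-16; 8 members past the threshold adjusted over the list alone), neurite outgrowth and synaptic vesicle genes (6.72e-05 each), neurotransmitters (2.6e-04), immediate early genes (3e-04) and unfolded protein response (8.35e-04). Others were cholesterol biosynthesis (0.00471), ion channels (0.00681), reactive glia (0.00897), glycolysis (0.0215) and p53 targets (0.0325). None passed with an estimated correlation, where the smallest adjusted p was 0.0997. Between classes, glia-like minus neuron-like, Resp18 again passed alone (6.41, SE 1.09, adjusted p = 0.0107), and Gal had 5.37 (adjusted p = 0.0765). Immediate early (7.36e-06), unfolded protein (7.36e-06) and neurotransmitter genes (0.0209) differed in camera, with adjusted p of 0.468, 0.258 and 0.285 with an estimated correlation. Neuron markers did not pass in camera between classes (adjusted p = 0.106). The class sums leave out the 4 neuron-like wells on CD49b+ plates, and also irradiated CD49b+ replicate 1.

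With the mouse pool as a block the interaction called 0 genes between gates (542 at an unadjusted p below 0.05) and 7 between classes, and the reactive glia (adjusted p = 0.0530), neurotransmitter (0.0586) and glycolysis (0.0681) lists no longer passed. The gate count was 0 without the 4 neuron-like wells or without homeostasis replicate 1, 2 or 3 or irradiated replicate 2, 2 without irradiated replicate 1, 76 without irradiated replicate 3, 33 with DESeq2, 67 without a filter, and 4 and 5 with the run set and the age as a term, and the class count was 0 without homeostasis replicate 1, 2 or 3 or irradiated replicate 2 (Resp18 −2.59 without the latter) and with the unnamed clusters put with their class.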

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

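The tests of neuron-like wells, of carried-over RNA and of genes switched on in glia were chosen after the result was seen. Resp18, a gene of neuroendocrine secretory granules, was picked out because its response to irradiation differed between the gates. The difference in log2 fold change was 8.585 between CD49b+ and CD49b− plates (edgeR adjusted p = 0.0326) and 6.4074 between glia-like and neuron-like cells (adjusted p = 0.0107). It had 0, 1 and 0 UMIs on homeostasis CD49b+ plates and 187, 262 and 0 on irradiated ones. CD49b− plates held 1700 to 2355. In the glia-class wells of irradiated replicates 1, 2 and 3 Resp18 stood at 575.5, 301.2 and 0 CPM. In the neuron-like wells of replicates 1 and 2 it stood at 3839 and 5334 CPM. Without those neuron-like wells the gate interaction no longer called it. Over the alternatives the plate value ran from 7.26 to 11.39 (adjusted p 1.15e-40 to 0.505, past the threshold in 10 of 17), and the class value from −2.59 to 9.20 (past it in 11 of 18). Of the 10 splits of the 6 pools, 3 gave at least the 1 gene of the interaction, and the highest of the others gave 6, with homeostasis replicate 1 and irradiated replicates 1 and 2 on 1 side. The 10 splits are too few for a share under 0.05.

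Resp18 belongs to the 44 genes that were higher on irradiated CD49b+ plates and lower in CD49b+ than in CD49b− cells, a pattern that went with the 2 plates that held neuron-like wells. Leaving out those 4 wells, which are also the wells above 3 times their plate median, left 5 of the 44 called (Cartpt, Gal, Npy, Resp18 and Tmem176b), so that neuron-like wells may account for part of the pattern; as the whole source of the folds they stay open, since the median log2 fold change of the 44 went from 3.946 (median SE 0.864) to 2.194 (0.903), all 44 stayed positive, and the calls ended with smaller folds at a like error (Snap25 3.90 to 1.61, Stmn2 5.29 to 3.43, Tro 3.98 to 3.41). RNA of those wells carried into other wells of the same plate stays open: neuron-side genes made up 1.115% and 1.173% of UMIs in the glia-class wells of those plates against 0.2956% on irradiated replicate 3 and 0.273% to 0.3175% in homeostasis, and over 565 such genes those wells resembled the neuron-like wells of their own plate more than those of the other by a rank correlation difference of 0.180 on replicate 1 (95% bootstrap interval 0.0987 to 0.265) but 0.0554 on replicate 2 (−0.0256 to 0.138). Neuron genes switched on in irradiated glia, the biological reading the design allows, also stays open. In glia-class wells alone 16 of the 44 lay higher on all 3 irradiated than on all 3 homeostasis plates. This is 36.4% against the 5% that chance gives, but the genes were picked because they were higher, so it is no support. On replicate 3, the irradiated plate without neuron-like wells, neuron-side genes as a whole stayed at 0.2956%, within the homeostasis range. That is 1 plate and does not settle single genes. Single genes go both ways: in glia-class wells of irradiated replicates 1, 2 and 3 Gal stood at 31.3, 7122 and 19.9 CPM, Cartpt at 3909, 34.0 and 6.64 and Grp at 782, 4.86 and 0, following the neuron-like wells of replicates 1 and 2 (Gal 40.4 and 123800, Cartpt 19400 and 373, Grp 5778 and 0), whereas Npy stood at 550, 670 and 385 CPM against 40.4 and 0 in those wells.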

How the results depend on the processing

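The alternatives without the 4 neuron-like wells and with the unnamed clusters put with their class were chosen after seeing the data; no cause was tested except where an alternative's construction shows it. CD49b+ plates held at most 245922 UMIs, and at the depth and number of plates had, the test recovered 13 of 100 simulated changes of 2-fold in them and 2 of 100 in the interaction. Depth limits how many genes can be tested, 8555 for the gate and 2417 with thinned wells. Of the 3198 values of named genes under alternatives, 2709 kept their direction and their side of the threshold, 441 kept their direction but lost the call, 22 gained it and 26 changed sign. The counts of genes stayed within 1.5 times their value in 16 of 17 alternatives for the gate, 13 of 17 for irradiation in CD49b− plates, 5 of 17 in CD49b+ plates, 4 of 17 for the interaction, 7 of 19 in neuron-like cells, 9 of 18 in glia-like cells and 3 of 18 for the class interaction. All wells with at least 1 UMI left no glia-like sums, so that this alternative was not possible for glia-like cells or the class interaction. With the mouse pool as a block, Xiap lost its call for the gate (adjusted p 0.0378 to 0.147 over 16 alternatives, called in 7). Resp18 lost its call in the gate interaction (1.15e-40 to 0.505 over 17, called in 10), and Gal gained one in the class interaction (4.57e-65 to 0.9998 over 18, called in 9). The block changed no other call of a named gene.

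With each well thinned to 1000 UMIs, which leaves fewer counts, the gate gave 1561 genes of 2417 tested (5311 of 8555 without thinning), irradiation 0 in CD49b− plates (98 at an unadjusted p below 0.05), 18 in CD49b+ plates, 3 in neuron-like and 17 in glia-like cells, and the class interaction 2. Without a filter beyond 1 count in total, irradiation gave 45 genes in CD49b− plates, 146 in CD49b+ plates, 38 in neuron-like and 48 in glia-like cells, and the interactions 67 (gates) and 7 (classes). DESeq2 gave 112 genes for irradiation in CD49b+ plates, 33 for the gate interaction and 6 in neuron-like cells. With only the 2 groups compared in the fit, irradiation gave 7 genes in CD49b− plates, 10 in CD49b+ plates, 5 in neuron-like and 17 in glia-like cells. With the run set as a term it gave 30 in CD49b+ plates, 6 in neuron-like and 4 in glia-like cells, and the interactions 4 and 5. With the age as a term each interaction gave 5. Without wells above 3 times their plate median, which are the same wells as the 4 neuron-like ones, irradiation gave 22 genes in CD49b+ plates and the gate interaction 0; without neuron-like wells on CD49b+ plates the values were the same 22 and 0. With the mouse pool as replicate block the gate interaction gave 0 genes (542 at an unadjusted p below 0.05) and the class interaction 7. Neuron-like cells gave 5 genes with all wells of at least 1 UMI and 6 with stricter wells, where the class interaction gave 3; Leiden resolution 0.5, or the unnamed clusters put with their class, gave 3 genes in neuron-like cells and 0 in the class interaction, and resolution 2.0 gave 15 in glia-like cells and 2 in the class interaction. Leaving out each pool in turn, the gate gave 4994 to 5589 genes. Irradiation gave 3 to 17 in CD49b− plates (17 without irradiated replicate 1). It gave 3 to 144 in CD49b+ plates (13, 5 and 3 without homeostasis replicates 1, 2 and 3; 24 and 144 without irradiated replicates 2 and 3). In neuron-like cells it gave 6 to 35 (7 and 6 without homeostasis replicates 1 and 2; 35 without irradiated replicate 1). In glia-like cells it gave 9 to 32 (18, 17 and 18 without the homeostasis replicates; 9 without irradiated replicate 2). The interactions gave 0 to 76 (gates) and 0 to 3 (classes). Both were 0 without any homeostasis replicate or irradiated replicate 2; without irradiated replicates 1 and 3 they were 2 and 76 (gates) and 3 and 2 (classes). Where this leaves 1 glia-like sum, it is assumed to vary like the other groups. In the same way the difference in neuron-like share between the gates was −91.766 to −89.748 percentage points and in glia-like share 79.328 to 98.459, where 5 pools allow no exact permutation p below 0.0625. The neuron-like difference was −43.972 with stricter wells, −56.597 with wells of at least 500 UMIs, −85.781 at Leiden resolution 2.0 and −99.163 at 0.5. The glia-like difference was 82.978, 83.153, 56.871 and 99.163 in the same order. The smaller values arose where more clusters with neuron or glia markers stayed unnamed.

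Of the gene lists, with an estimated correlation 0 passed for irradiation in CD49b− plates (5 at the preset one), 1 in CD49b+ plates (11), 0 in neuron-like cells (6), 1 in glia-like cells (7) and 0 for the interactions of gates (11) and classes (3). With fry, which asks another question, 0 passed in CD49b− plates, 5 in CD49b+ plates, 0 in neuron-like cells and 0 for either interaction; with thinned wells, 1 in CD49b− plates, 6 in CD49b+ plates, 5 for the gate interaction and 4 in glia-like cells, with fewer genes tested. With the mouse pool as replicate block and an estimated correlation 6 lists passed for the gate (16 at the preset correlation and 12 with the estimated one) and 0 for either interaction.

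Of the named genes past the threshold, the log2 fold change changed sign, with the run set as a term, for Gm19244 in neuron-like cells (−0.17) and, in glia-like cells, for Gfap (−0.49), Ifi27l2a (−0.73) and Ptx4 (0.26), and for Gm12155 in neuron-like cells with thinned wells (−0.0914). Others changed sign without irradiated replicate 2, the plate that held 3 of the neuron-like wells. Over the pools left out, Gal ran from −0.21 to 9.11 on CD49b+ plates and from −0.71 to 7.84 in glia-like cells. Resp18 ran from −2.66 to 9.06 in glia-like cells and from −2.59 to 9.20 in the class interaction, where Gal, not past the threshold, ran from −2.30 to 6.21. The other changes of sign were in genes not past the threshold. With thinned wells Dclk1 (−0.186), Fos (−0.0629) and Prph (−0.0560) changed sign in CD49b− plates, and Dclk1 in neuron-like cells (−0.225). There Dclk1 also did with all wells of at least 1 UMI (−0.0588) and at Leiden resolution 2.0 (−0.0426). With the run set as a term Fos in CD49b− plates (−0.0187) and Itga2 on CD49b+ plates (−0.493) did, and with the age as a term Itga2 on CD49b+ plates (−0.184) and in glia-like cells (−0.174). Over the pools left out, in CD49b− plates Fos ran from −0.114 to 0.238 (negative without homeostasis replicate 1 or irradiated replicate 1), Ifi27l2a from −2.05 to 4.52 (positive without homeostasis replicate 3) and Prph from −0.0680 to 0.186 (negative without irradiated replicate 3). Itga2 ran from −0.210 to 1.10 on CD49b+ plates and in the gate interaction (negative without homeostasis replicate 3). The cause was not tested; for glia-like cells the offset of set B comes from CD49b− plates.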

Other observations

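Mki67, a protein of dividing cells, had 1 UMI on homeostasis CD49b− replicate 1 and 1 on homeostasis CD49b+ replicate 2, and 0 on the 6 irradiated plates, where 3 counts would be 4.04 to 19.9 CPM. Pcna of the cell cycle list stood at 61.7 ± 18.8 and 68.4 ± 14.7 CPM on homeostasis and irradiated CD49b− plates and at 64.5 ± 37.9 and 35.2 ± 6.31 on CD49b+ plates (SD, n = 3). C1qa, a complement gene of macrophages, had 0 UMIs on all 12 plates, and Csf1r, the receptor of the macrophage growth factor, 1 UMI on each of 2 CD49b− plates and 0 on CD49b+ plates. Cd74 was detected in 106 of 223 homeostasis and 148 of 213 irradiated CD49b+ wells, and Cd14 in 30 and 19. Dcn, a proteoglycan of fibroblasts, was detected in 13 of 262 homeostasis and 19 of 266 irradiated CD49b− wells and in 0 CD49b+ wells. Replicate 3 carried this in each treatment (14.3% of its wells in homeostasis and 20% after irradiation, against 0% and 0% and 2.17% and 0% in replicates 1 and 2). Among CD49b− wells the clusters led by Calb2 (38.9% ± 8.48 and 31.9% ± 9.10 in homeostasis and after irradiation, SD, n = 3), Npy (14.98% ± 1.91 and 14.97% ± 2.79), Tac1 (15.03% ± 4.76 and 15.8% ± 5.26) and Cartpt (23.6% ± 10.8 and 26.5% ± 10.4) did not differ by more than the spread (exact permutation p = 0.4, 1, 0.7 and 0.8; smallest possible 0.1).

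With every well put with the class whose markers it held, an alternative chosen after seeing the data that restores irradiated replicate 1, lists shifted up in irradiated glia with an estimated correlation as well: reactive glia (adjusted p = 0.00301, 2 of 8 genes past the threshold), p53 targets (0.0356, 1 of 12), antigen presentation (0.0365, 4 of 14), interferon response (0.0453, 1 of 16) and the unfolded protein response (0.0456, 0 of 11). In neuron-like cells put together in the same way, the interferon list had 0 of 16 genes past the threshold and an adjusted p of 0.185 with an estimated correlation. The difference between the classes had adjusted p of 0.106 for reactive glia and 0.939 for interferon response with an estimated correlation.

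Of the tests below, those on shared words and on other splits of the samples were set before the result was seen, and the others after. For the gate, where a fit of gate and treatment without their interaction, used for the splits, gave 5271 genes, 1 of 100 splits of the plates, the real one, gave as many, and the highest other gave 0, so that chance can be excluded. Among the 32 splits that part every pool 1 did, the real one, with the highest other again 0. For irradiation in CD49b− plates the real split gave 4 genes and the highest of the other splits 1 (1 of 10 as large), in CD49b+ plates 61 and 36 (1 of 10), and in neuron-like cells 12 and 15 (2 of 10). The 10 splits are too few for a share under 0.05. The split with 36 genes set homeostasis replicate 1 and irradiated replicates 1 and 2, which include both plates with neuron-like wells and both plates of run set A, against the rest. The split with 15 set homeostasis replicates 1 and 2 and irradiated replicate 1 against the rest. With the run set as a term the counts were 30 and 6.

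The repeat-like gene models Gm10800, Gm10801 and Gm21738 were higher in irradiated CD49b− plates; with the other models of their family they made up 2.52 ± 1.79 and 327 ± 137 CPM on homeostasis and irradiated CD49b− plates and 21.5 ± 22.6 and 119.3 ± 47.4 on CD49b+ plates. A difference between run sets as the whole cause is argued against, since 3 of 3 models stayed called with the run set as a term. That fit rests on 1 pool of each treatment, whose plates helped to pick the models, so it does not tell treatments from pools. Free nucleic acid in the sorted suspension would reach the wells of both gates alike. CD49b− wells held more of these UMIs than CD49b+ wells of the same pool by ratios of 9.158, 13.4 and 3.258 (95% intervals 5.73 to 15.5, 8.52 to 22.3 and 2.12 to 5.19, median 9.158). Per UMI of the plate the ratios were 4.16, 4.66 and 0.991. This argues against free nucleic acid as the whole source in replicates 1 and 2, if wells of both gates captured molecules alike. Replicate 3 leaves it open, since its CD49b− wells held no more of these UMIs than their depth gives. Reads shared between near-identical gene models stay open, since at least 36.19% of the 31-base words of each model occur in another, between the bounds set for and against; this concerns which copy rose, and sharing alone gives no difference between treatments. That irradiation raised transcripts of this repeat family in neurons remains a candidate explanation, a hypothesis found and tested on the same plates.

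The other 13 genes higher on irradiated CD49b+ plates (among them Serpina3n, Cdkn1a, Gfap, H2-Aa, Psmb8 and Bst2) were not lower in CD49b+ than in CD49b− cells. Their calls did not rest on the neuron-like wells, since 13 of 13 stayed called without them. This is no test of those wells as a cause, as genes not lower in CD49b+ cells could hardly lose their fold that way. With the run set as a term the median log2 fold change was 1.905 (median SE 0.387) against 1.635 (0.293), and with the larger error 4 of 13 kept their call. A difference between run sets as the whole cause is not settled by this. That fit rests on 1 pool of each treatment, whose plates helped to pick the genes. The rise did not rest on wells with a UMI of a macrophage marker other than Cd74 (22 irradiated and 32 homeostasis wells). By a test added after the values were seen, the median log2 ratio of the 13 genes was 1.532 without these wells against 1.516 (1.364 to 1.64 with each plate left out). These wells were few of the 213 irradiated CD49b+ wells. Most of them held Cd14, and none was identified as a macrophage. All 209 irradiated glia-class wells held a UMI of a glia marker. This argues against wells of macrophages alone as the source, unless glial RNA reached them from other wells. Macrophages that shared a well with a glial cell and left no macrophage marker UMI stay open. The macrophage markers other than Cd74 stood at 0.2646 times their homeostasis level, but Cd14 carried this. The others had 3 UMIs on irradiated and 2 on homeostasis plates (ratio 1.41, 95% counting interval 0.161 to 16.9, against a median rise of 3.105-fold). A response of glia to irradiation, with p53-induced Cdkn1a and interferon-induced genes, remains a candidate explanation, as a hypothesis found and tested on the same plates, since pools and plates differ between the treatments and replicates 2 and 3 of each treatment shared no run set with the other.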
